A study of Mus musculus with 6 samples.

How the data were processed

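RNA was measured by sequencing in MC3T3-E1 cells, an established mouse osteoblastic cell line. The labels name a control line and a line edited with CRISPR in Rorβ, a retinoid-related orphan nuclear receptor, each with 3 replicates. All cells had been kept for 2 days in a medium that promotes osteoblast differentiation. Per the labels' protocols, total RNA was extracted with Trizol, cleaned and treated with DNase, and libraries were made with an Encore NGS kit. The labels do not give the strand, the read length, the guide sequence or the number of edited clones.

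The submitters' processing notes name TopHat2 2.0.6, HTSeq and the mouse build mm9. The gene annotation, the counting options and the tool behind the deposited p-values are not given in the sources used here. The deposited table has 43346 rows by gene symbol, of which 18010 were at 0 in all 6 libraries. Its values per library are a signal scaled by the authors with trimmed-mean factors (TMM), as CPM of an effective library size, which fits the recovered reads, with TMM named per the file headers. The authors also deposited, for each group, the median count, the median scaled signal, a fold (ratio) between the groups, a p-value and a q-value. A spreadsheet had turned 27 symbols into dates, and 127 rows shared a symbol with another row. No rows of mitochondrial genes had reads, so a mitochondrial share could not be computed.

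In each library 100% of the values were whole multiples of the value of 1 read, within 0.01 of a whole number. Group medians of the reads recovered in this way equalled the deposited median counts in all 43346 rows. Reads in genes per library then ranged from 34662707 to 42603315. Counting intervals and floors cover counting error only, since the labels name no molecular identifiers.

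The design had planned edgeR's quasi-likelihood test on counts. Because the values per library were scaled and not counts, the planned fallback was used: limma-trend with robust moderation on log2(value + 1), for rows with a value of at least 1 in at least 3 libraries. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of genes with low values. The comparison used all 6 libraries and no covariate. In simulated data with 13412 tested genes and a fold of 1.2, 1.5, 2 or 4, the test recovered 38.8%, 94.0%, 100% and 100% of the changed genes, with 7 false calls. A simulated shift of the cell cycle list by a fold of 1.5 was called, and 0 other lists were called. The simulated genes were drawn independently with a shared dispersion, and the gene simulation changed a small set equally in both directions. In the real lists the estimated correlation reached 0.411 (cholesterol synthesis), and most tested genes were called. The simulations therefore do not show how the tests perform with correlated lists or such wide changes.

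Before the data were examined, 31 gene lists were fixed from general knowledge of bone cells, signalling pathways and other cell types. The 30 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Camera compares a list with all other genes. Fry's directional p tests whether the genes of a list move one way on balance, and its mixed p whether they change in either direction. The rule for named genes was also fixed beforehand. It took Rorb, then the 12 highest and 12 lowest fold changes among called genes with a mean value of at least 1 and no overlap between the groups. Predicted and unnamed gene models were left out. In each list it took up to 4 called members of smallest adjusted p, or, with fewer than 2 called, members of highest mean value to make 2. Genes named outside that rule are said to be chosen after their values were seen.

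Alternatives planned beforehand were DESeq2 size factors, upper quartile factors, library size only, no filter, a CPM filter, pseudocounts of 0.1 and 0.5, a replicate block, leaving out replicates, an adjusted p of 0.01, a test against a fold of 1.5, DESeq2 and limma-voom. A test on the authors' normalized values, also planned, became the reported test itself. Added after seeing the data were edgeR's quasi-likelihood test on the recovered reads, chromosome centring, and TMM without 3 rows that carry ribosomal RNA reads. Chromosomes were taken by gene symbol from the RefSeq annotation of GRCm38.p6, which matched 12537 of 13498 tested genes (92.9%). The design would have run the chromosome summary only on chromosomes given in the table, so its use of the annotation was also added. Because the authors' build differs, no coordinates are given.

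Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.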

Results

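Transcript levels were measured in MC3T3-E1 cells, a mouse osteoblastic line, after 2 days of differentiation. There were 3 control libraries and 3 libraries labelled Rorβ-CRISPR, from cells edited in the nuclear receptor gene Rorb. Reads in genes numbered 42603315, 40772380 and 41896283 in the control libraries and 34662707, 42255967 and 40487707 in those labelled Rorβ-CRISPR. Values are CPM scaled by the authors with TMM factors. Errors are SDs over 3 libraries unless given as SE. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Pearson's r of log2 values across genes was 0.99726 to 0.99797 within groups and 0.96854 to 0.96952 between them. Genes are not independent replicates.

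The targeted gene was examined first. Rorb reads numbered 1, 3 and 0 in the control libraries and 69, 78 and 111 in the libraries labelled Rorβ-CRISPR. The ratio of summed reads per effective library size was 58.8, with an exact 95% counting interval of 22.7 to 217. Rorb values averaged 0.035 ± 0.040 in control and 2.03 ± 0.435 in the labelled libraries (SD, n = 3 each; limma-trend log2 fold change 1.54, SE 0.128, adjusted p = 3.12e-15). With a pseudocount of 0.1 or 0.5 in place of 1, the log2 fold change of Rorb was 3.999 or 2.23. The authors' deposited table gives a fold of 54.0 with q = 1.75e-39. Rorb RNA was therefore higher in every library labelled as a knockout than in any control library. All 3 control libraries lay below the filter value of 1, with 4 Rorb reads in total. As labelled, the control cells thus held little Rorb RNA that an edit could have removed. Reads counted per gene do not show the edited bases, and an edit that disrupts the protein need not lower the RNA. Every direction below is between libraries as labelled. The related gene Rora fell from 90.2 ± 2.27 to 32.7 ± 2.03.

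**Figure D1:**
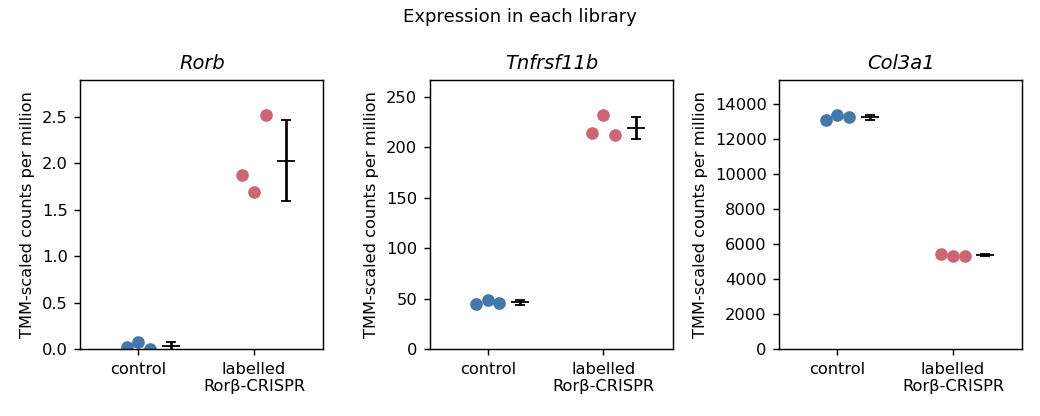
TMM-scaled CPM of Rorb, Tnfrsf11b and Col3a1 in each control library (blue) and each library labelled Rorβ-CRISPR (red), with a bar for the mean ± SD of 3 libraries. Rorb and Tnfrsf11b lay above all control libraries in the 3 labelled libraries, and Col3a1 lay below.

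The comparison asked which genes differ between the control line and the line labelled as edited in Rorb. The labels name only these lines, so effects of the edit cannot be told apart from other differences between the lines. In the libraries labelled Rorβ-CRISPR, Igfbp5, which encodes a binding protein of insulin-like growth factors, fell from 712 ± 27.2 to 12.4 ± 1.00 (log2 fold change -5.74, SE 0.041, adjusted p = 1.86e-40). Entpd3, an ectonucleotidase gene, fell from 40.4 ± 2.19 to 0.140 ± 0.089. Smooth muscle gamma actin (Actg2), elastin (Eln) and the endothelin receptor gene Ednra fell, with log2 fold changes of -4.37, -4.23 and -3.84. Edil3, Tspan7, Abi3bp, Megf6, Apod, Tagln and Enpep completed the 12 lowest, with log2 fold changes of -3.83 to -3.28. Of the 12 highest genes on the log2(value + 1) scale, Col4a6, a basement membrane collagen gene on chromosome X, came first. Col4a6 rose from 2.17 ± 0.075 to 67.5 ± 1.35 (limma-trend log2 fold change 4.43, SE 0.069, adjusted p = 1.06e-45). Its log2 fold change was 3.78 after chromosome centring. Scn3a, a sodium channel gene, rose from 5.37 ± 0.124 to 77.1 ± 3.57. Smpd3, a sphingomyelinase gene needed for bone mineralization, rose from 30.8 ± 1.34 to 298 ± 7.32, and the imprinted gene Mest rose from 37.6 ± 3.82 to 316 ± 8.85. Fam135b, Spock2, Marcksl1, Ramp1, Cdh22, Prrg1, Als2cl and Gpr116 completed the 12 highest, at 3.55, 3.52, 3.43, 3.25, 3.14, 3.10, 3.07 and 2.86. The order depends on the pseudocount. With 0.1 in place of 1, Marcksl1 (5.96) and Fam135b (5.53) lay above Col4a6 (4.89), and Entpd3 (-7.46) lay below Igfbp5 (-5.84). Among 13498 tested genes, 4441 were higher and 4501 lower at an adjusted p of 0.05 (limma-trend), which was 66.2% of those tested. On the log2(value + 1) scale, 7076 of these called genes differed by a fold under 1.5. On the same scale 196 were higher and 368 lower by a fold of 2 or more. The groups did not overlap in 68.4% of the tested genes, where chance gives 10%. Scaled by library size only, which shifts the median gene by 0.21 (log2), 7291 genes were higher and 1975 lower (78.7% of calls higher, against 49.7%). Tested against a fold of 1.5, 413 genes were higher and 645 lower.

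**Figure D2:**
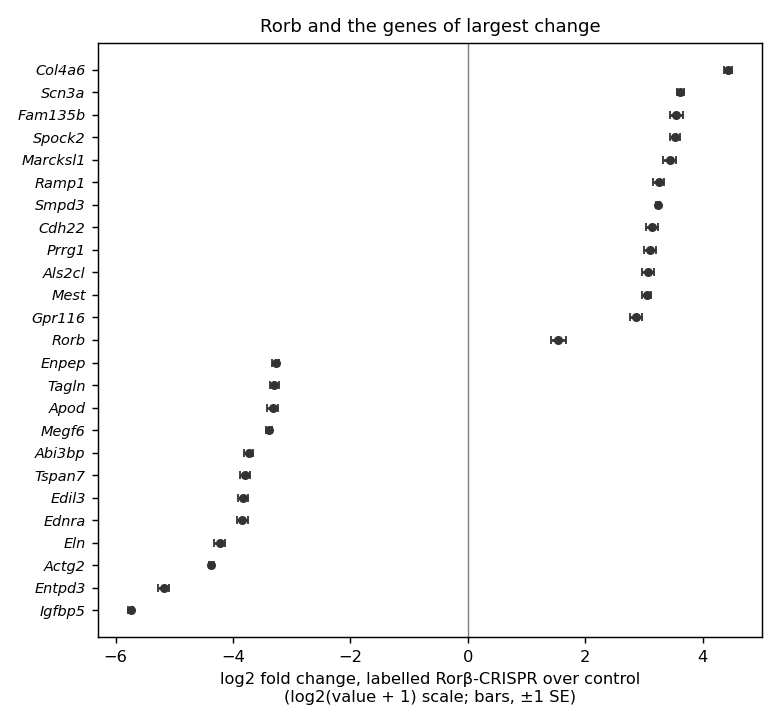
Log2 fold change, libraries labelled Rorβ-CRISPR over control, on the log2(value + 1) scale, for Rorb and the 12 highest and 12 lowest genes of the naming rule, with bars of ±1 SE from limma-trend. On this scale Igfbp5 was lowest at -5.74 and Col4a6 highest at 4.43.

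Genes shifted together by chromosome (GRCm38.p6 annotation). Relative to all tested genes, the median log2 fold change in the libraries labelled Rorβ-CRISPR was largest in size on X, 14 and 15, leaving out chromosome Y with its 4 tested genes. It was 0.64 for 433 genes of chromosome X, of which 359 were higher and 23 lower. It was -0.53 for 399 genes of chromosome 14 (14 higher, 339 lower) and -0.27 for 472 genes of chromosome 15 (52 higher, 319 lower). Of the 196 genes higher by a fold of 2 or more on the log2(value + 1) scale, 70 (35.7%) lay on chromosome X. That chromosome held 3.2% of the tested genes. Of the 368 genes lower by that fold, 55 (14.9%) lay on chromosome 14 or 15, which held 6.5%. Chromosome 5 lay at 0.21 (485 higher, 101 lower), chromosome 13 at 0.20 (264 higher, 77 lower) and chromosome 1 at 0.12. All 4 tested genes of chromosome Y were higher, with a median of 0.35. The exact permutation p of medians per library (two-sided) was 0.1, adjusted 0.111, on 19 of 21 chromosomes, some with almost no shift, and 0.1 is the smallest p that 3 against 3 libraries allow. Another measured difference was the share of reads in 3 rows known to collect ribosomal RNA reads (Yam1, AY036118 and Lars2). It was 25.4%, 17.9% and 16.9% in the control libraries and 15.2%, 13.1% and 13.9% in those labelled Rorβ-CRISPR.

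**Figure D3:**
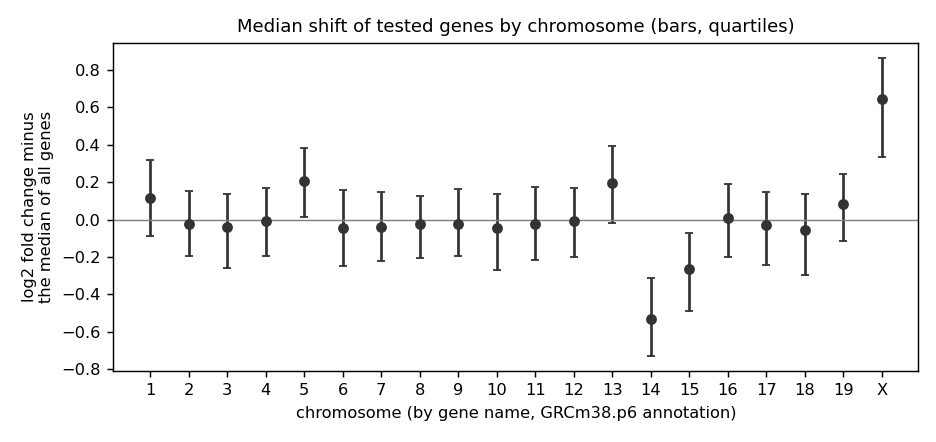
Median log2 fold change of the tested genes of each chromosome, libraries labelled Rorβ-CRISPR over control, minus the median of all tested genes, with bars from the lower to the upper quartile of genes. Chromosome X lay at 0.64, chromosome 14 at -0.53, chromosome 15 at -0.27, chromosome 5 at 0.21 and chromosome 13 at 0.20.

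Genes of the extracellular matrix were lower in the libraries labelled Rorβ-CRISPR. Of 38 tested collagens and structural matrix genes, 35 fell, 2 rose and 1 was not called, with a median log2 fold change of -0.86. Lox, which encodes an enzyme that cross-links collagen, fell from 771 ± 11.9 to 140 ± 4.55. Postn and Col3a1 fell as well, at -1.72 and -1.30 (log2). The list was called by camera (adjusted p = 3e-13), but not with an estimated correlation (adjusted p = 0.126). Of 22 matrix proteases and inhibitors, 16 fell and 3 rose (camera adjusted p = 6.8e-05; adjusted p = 0.119 with an estimated correlation). Among them Mmp14, a membrane metalloprotease gene, fell from 727 ± 8.90 to 244 ± 8.58, and Plat, the tissue plasminogen activator gene, from 74.3 ± 2.62 to 14.2 ± 0.899. Mmp14 lies on chromosome 14. All 15 smooth muscle and contractile genes fell (camera adjusted p = 1.08e-07; adjusted p = 0.232 with an estimated correlation), among them Acta2 from 1434 ± 25.3 to 663 ± 25.1. All 10 tendon and fibroblast markers fell (camera adjusted p = 7e-04; adjusted p = 0.119 with an estimated correlation), including the platelet-derived growth factor receptors Pdgfra and Pdgfrb at -0.93 and -0.75. Col1a1 and Col1a2 are also part of the osteoblast list, so lists share members. None of the 9 lists called by camera with the preset correlation passed with an estimated one, which gave 0 calls at the adjusted threshold and 7 at an unadjusted p under 0.05, while fry's directional test called 26 lists. All 9 were lower, and their medians were also below 0 with library size only and after chromosome centring. With library size only some came near 0. The median of the nuclear receptor list went from -0.29 to -0.07 and that of the cholesterol synthesis list from -0.31 to -0.09. Among the 9 lists, the estimated correlation was 0.411 for cholesterol synthesis, 0.369 for contractile, 0.156 for structural matrix and 0.044 for interferon-stimulated genes. It lay below the preset 0.01 for proteases (-0.021), insulin-like growth factors (-0.023), clock (-0.015), nuclear receptors (-0.006) and tendon and fibroblast markers (-0.061). A correlation above the preset therefore does not account for the lost calls of these last lists.

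**Figure D4:**
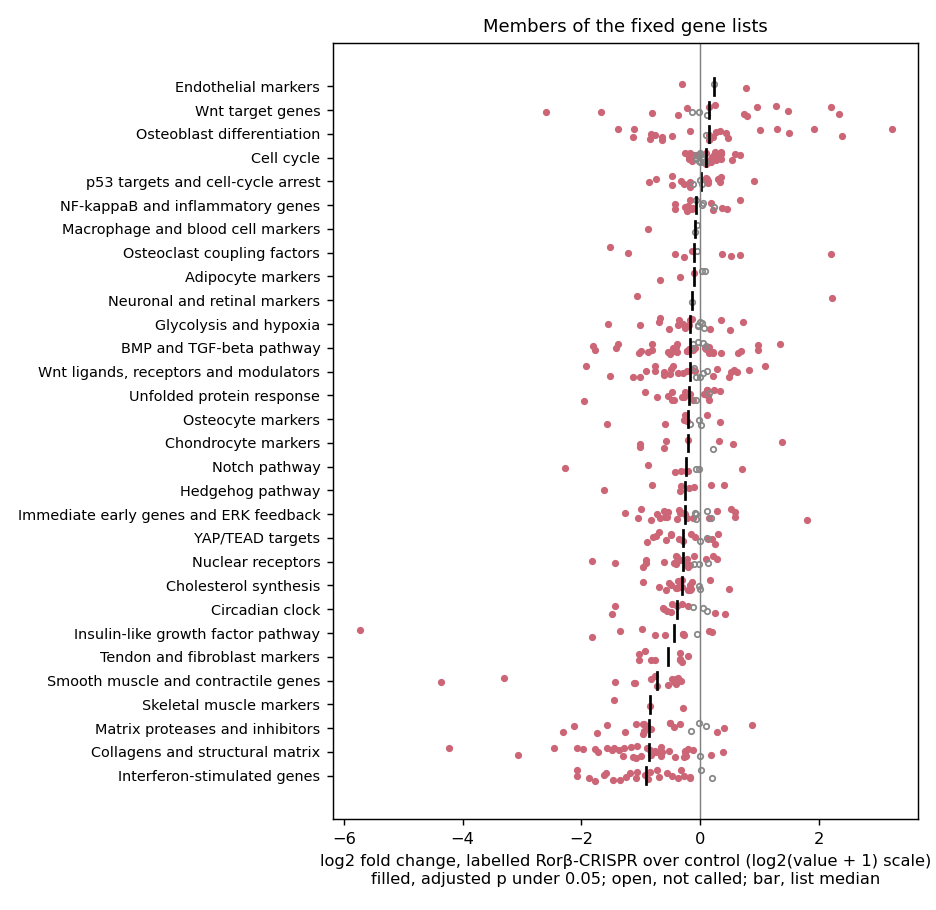
Log2 fold changes of the tested members of each of the 30 tested lists, libraries labelled Rorβ-CRISPR over control, on the log2(value + 1) scale. Filled points passed an adjusted p of 0.05, open points did not, and bars are list medians, from -0.91 for interferon-stimulated genes to 0.23 for endothelial markers, 11 of which turn from below to above 0 when scaled by library size only.

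Bone cell genes moved in both directions in the libraries labelled Rorβ-CRISPR. Of 24 osteoblast differentiation genes, 13 rose and 10 fell (median 0.16, camera adjusted p = 0.522). That median was 0.09 after chromosome centring, with 12 higher and 11 lower, and 0.38 with library size only. Ibsp, which encodes bone sialoprotein, rose from 128 ± 3.82 to 492 ± 26.7, alongside Smpd3. Col1a2, a chain of type I collagen, fell from 30530 ± 339 to 17250 ± 267, and Sparc, the osteonectin gene, fell from 6748 ± 113 to 4335 ± 62.2. Chosen after their values were seen, the mineralization gene Phospho1 rose from 52.8 ± 3.18 to 151 ± 5.93. Also chosen so, Alpl (alkaline phosphatase) and Ifitm5 rose by 1.01 and 2.39 (log2), and the osteocalcin genes Bglap and Bglap2 fell, at -1.11 and -1.39. Among 10 osteocyte markers, 2 were higher and 5 lower (camera adjusted p = 0.134). Of 10 genes for osteoclast coupling factors, 4 were higher and 5 lower (camera adjusted p = 0.987, with a median of -0.09, a mean of 0.02 and an upward test). In that list Tnfrsf11b, which encodes osteoprotegerin, the decoy receptor that limits osteoclast formation, rose from 46.5 ± 2.34 to 219 ± 11.1 (log2 fold change 2.21, SE 0.037, adjusted p = 2.92e-40). Sema3a rose by 0.52 and Wnt5a, on chromosome 14, fell by 1.52. Tnfsf11, the gene of the osteoclast factor RANKL, chosen after its values were seen, had 0 reads in all 6 libraries, which allows up to 3 reads in each.

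Wnt target genes and Wnt pathway genes were not called as lists. Of 17 Wnt targets, 9 were higher and 5 lower (camera adjusted p = 0.249), in the libraries labelled Rorβ-CRISPR. Tcf7, a transcription factor gene of that pathway, rose from 19.6 ± 0.564 to 104 ± 7.74, and Myc from 67.6 ± 0.847 to 191 ± 3.96, while Dact1 fell from 60.1 ± 3.44 to 9.13 ± 0.393. Of 30 Wnt ligands, receptors and modulators, 8 were higher and 17 lower, or 18 lower when adjusted over the list alone (camera adjusted p = 0.113, or 0.0254 with library size only), with Wls and Lrp5 at -1.12 and -0.75. Of 38 BMP and TGF-beta genes, 12 were higher and 21 lower (adjusted p = 0.0746, or 0.0144 with library size only and 0.0155 without a filter), with Tgfbr1 at -0.99 and Chrdl1, on chromosome X, at 1.35. Genes of the insulin-like growth factor pathway fell in 9 of 12 members, or 10 when adjusted over the list alone, and rose in 2 (camera adjusted p = 0.00254; adjusted p = 0.126 with an estimated correlation). Igf1 fell from 431 ± 4.34 to 169 ± 9.53 and Igf2 from 10.7 ± 0.114 to 2.32 ± 0.483. Notch pathway genes were higher in 1 and lower in 6 of 9 (adjusted p = 0.0858), Notch3 at -2.28. The Hedgehog list had 2 higher and 6 lower of 8 (adjusted p = 0.132), and the YAP/TEAD targets 4 higher and 11 lower of 17 (adjusted p = 0.0545). Of 28 immediate early genes and ERK feedback genes, 6 were higher and 17 lower (adjusted p = 0.0538), Klf2 at 1.80 and Dusp1 at -1.25. In the other lists of these 30 the counts were the same when adjusted over the list alone, except p53 targets (9 lower instead of 8), chondrocyte markers (4 higher instead of 3) and endothelial markers (2 higher instead of 1).

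Interferon-stimulated genes were lower in the libraries labelled Rorβ-CRISPR, with 24 of 26 lower, 0 higher and a median of -0.91 (camera adjusted p = 1.04e-07; adjusted p = 0.119 with an estimated correlation). Isg15 fell from 8.72 ± 1.83 to 1.28 ± 0.162, and Stat2 and the class I histocompatibility gene H2-D1 fell, at -0.93 and -1.08. The 17 NF-kappaB and inflammatory genes had 5 higher and 8 lower (adjusted p = 0.979, median -0.07, mean 0.01). Of 24 nuclear receptor genes, 18 fell and 3 rose (camera adjusted p = 0.00121; adjusted p = 0.119 with an estimated correlation). Besides Rora, Vdr, the vitamin D receptor gene, on chromosome 15, fell, with a log2 fold change of -1.82. After chromosome centring 15 of the nuclear receptor genes were lower and 5 higher. Circadian clock genes fell in 10 of 15 and rose in 2 (camera adjusted p = 0.0144; adjusted p = 0.164 with an estimated correlation). Arntl, a core activator of the clock, fell from 30.2 ± 1.52 to 10.2 ± 0.407.

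Cholesterol synthesis genes fell in 17 of 21 and rose in 2 in the libraries labelled Rorβ-CRISPR (camera adjusted p = 0.00177; adjusted p = 0.452 with an estimated correlation). Fdft1, on chromosome 14, was at -0.96, and Srebf2 and Sqle, on chromosome 15, at -0.57 and -0.50. Glycolysis and hypoxia genes were higher in 4 and lower in 12 of 21 (adjusted p = 0.105), and unfolded protein response genes in 7 and 13 of 22 (adjusted p = 0.112). Cell cycle genes were higher in 18 and lower in 6 of 35 (adjusted p = 0.0545), Mcm6 rising by 0.68. The p53 targets had 9 higher and 8 lower of 20 (adjusted p = 0.759, median 0.02, mean -0.05), with Cdkn1a at -0.46.

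Markers of other cell types were tested where they passed the filter, and with the reported scaling no such list was called between the libraries labelled Rorβ-CRISPR and control, apart from the contractile and fibroblast lists above. Chondrocyte markers were higher in 3 and lower in 5 of 9 (adjusted p = 0.614), adipocyte markers were lower in 3 of 5 (adjusted p = 0.249) and all 3 tested skeletal muscle markers were lower (adjusted p = 0.0876, or 0.00453 with library size only). After chromosome centring 2 of these 3 were lower and their median went from -0.84 to -0.32. Macrophage and blood cell markers had 1 lower of 3 (adjusted p = 0.335), Lyz2 at -0.88. Endothelial markers had 1 higher and 1 lower of 3 (adjusted p = 0.746), and neuronal and retinal markers 1 higher and 1 lower of 3 (adjusted p = 0.97, median -0.13, mean 0.35), Tubb3 at 2.23 and Map2 at -1.06. After chromosome centring the neuronal and retinal list had 1 higher and 2 lower, with a median of -0.78. In the RNA quality list, too small to test, Neat1 was lower (107 ± 3.37 against 57.1 ± 6.36) and Malat1 was 957 ± 130 against 889 ± 68.8 (adjusted p = 0.53).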

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

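Leaving out replicates, singly or in numbered sets, gave 3929 to 4286 genes higher and 4072 to 4321 lower in the libraries labelled Rorβ-CRISPR, 9 to 12 lists called, and a Rorb log2 fold change of 1.40 to 1.65. That of Rorb was 3.999 and 2.23 with pseudocounts of 0.1 and 0.5, 5.87 with DESeq2, 5.82 with limma-voom and 5.76 with edgeR. With library size only, 7291 genes were higher, 1975 lower and 15 lists passed, and the median gene shifted upward by 0.21 (log2). In that scaling Dstn, Vcam1 and Fasn turned from below 0 to 0.008, 0.05 and 0.12 (not called). At an adjusted p of 0.01 the circadian list (0.0144) lost its call. Besides fry, the immediate early list gained a call in 8 settings on all libraries (adjusted p = 0.00643 to 0.0497), cell cycle in 5 (0.00955 to 0.0454) and YAP/TEAD in 3 (0.00711 to 0.0408), each among them with library size only, no filter and limma-voom. BMP and TGF-beta passed with library size only, no filter and chromosome centring (0.0144 to 0.0359). Wnt ligands (0.0254) and skeletal muscle (0.00453) passed with library size only, unfolded protein response (0.0339) without a filter and Notch (0.033) after chromosome centring. Without control 1, immediate early (0.034) and cell cycle (0.0482) passed, without control 3 YAP/TEAD (0.0439), without Rorβ-CRISPR 1 immediate early (0.0456), and without Rorβ-CRISPR 3 immediate early (0.0314), cell cycle (0.0238) and YAP/TEAD (0.0471). All 3 passed without both libraries numbered 3, and immediate early without both numbered 1. Without a filter on low values 14 lists passed. Tested against a fold of 1.5, 413 genes were higher and 645 lower. An estimated correlation left 0 lists and fry called 26. The cause of these differences was not tested, but in some called lists the estimated correlation lay below the preset one, as given above. A replicate block gave 4502 genes higher, 4551 lower and 9 lists, and ended no call of a named gene. Same-numbered libraries had correlated deviations of -0.056, 0.167 and 0.127. Control 1 correlated best with another number (0.059), while controls 2 and 3 correlated best with their own. These values do not decide whether the numbers pair samples, and the reported test used no pairing. Chosen after seeing the data, edgeR on the recovered reads called 4697 higher and 4726 lower, chromosome centring 4221 and 4274 (208 genes then called the opposite way), and TMM without the rows of ribosomal RNA reads 4634 and 4374. The chromosome shifts of X, 14 and 15 were 0.04, -0.25 and -0.09 without a filter, where many genes near 0 enter, and 0.61 to 0.70, -0.56 to -0.52 and -0.28 to -0.26 in the other settings, except chromosome centring, which removes them by construction. With library size only, 9 other named genes lost their call (Capg, Pdpn, Notch2, Axl, Cdon, Gli3, Zfp423, Flt1 and Acta1, at -0.129 to -0.024). Tested against a fold of 1.5, 40 did. Chromosome centring ended the calls of Dnajc3, on chromosome 14, and Acta1, and Acta1 lost its call in 12 settings in all, more than any other named gene. Medians of the osteoclast coupling, NF-kappaB and p53 lists were -0.17, -0.04 and 0.02 after chromosome centring and 0.13, 0.10 and 0.24 with library size only.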

Other observations

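The tests of Rora reads, of Rorb neighbours and labels, of Xist reads, of runs of neighbouring genes and of other splits were written down only after their results were seen. The genes and groups of this paragraph were chosen after their values were seen. In the libraries labelled Rorβ-CRISPR, 76 of 82 ribosomal protein genes rose and 0 fell (median log2 fold change 0.45), Rplp0 from 708 ± 18.1 to 1285 ± 5.99 (SD, n = 3 each). Of 65 genes with symbols that start with Eif or Eef and a digit, 43 rose, Eef1a1 by 0.59, and 7 fell. These symbols name translation initiation and elongation factors, and also any regulators of them that are named alike. Of 15 integrin genes 12 fell and 2 rose, Itga6 at -1.24. In the protocadherin beta cluster 14 of 16 genes fell and 0 rose (median -0.92). Ribosomal protein genes have pseudogenes and protocadherins close paralogs, so the split of reads among their rows is uncertain. Of 8 imprinted genes 6 fell and 2 rose (median -0.55), with Mest at 3.04 and Plagl1 at -2.98. Tmem158 varied widely within both groups, with 31035, 21681 and 237 reads in control and 77, 18056 and 86 in the labelled libraries (adjusted p = 0.422).

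Rorb reads were higher in the libraries labelled Rorβ-CRISPR, although their label names a knockout. Reads of the related gene Rora do not account for it, since Rora itself fell (log2 ratio of mean values -1.46). A copy gain of the region is argued against by 9 tested neighbours among the 10 on each side, with a median log2 fold change of 0.095 and a highest of 0.54. Exchanged labels of the 2 groups cannot be told apart from an edited line with more Rorb RNA. Either would give more Rorb reads in every labelled library than in any control library, and reads per gene show no edit. Changed transcription of an edited allele also stays open, as untested.

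Genes of chromosome X were higher (0.64) and those of chromosome 14 lower (-0.53), while 1000 random sets from the other chromosomes, matched on GC content, transcript length and expression, reached at most 0.060 and at least -0.022, which argues against these biases. Draws only from chromosomes with little shift, a pool used first and widened after its result was seen, gave at most 0.043 and at least -0.069. A switched-on inactive X is argued against by only 4 Xist reads over the 3 control libraries, though few Xist reads alone do not exclude it. Genes of chromosome Y had reads in every library, so both lines carried Y sequences. Summed over control and labelled libraries, Ddx3y had 16066 and 19155 reads and Kdm5d 5487 and 7828. Of runs of 20 neighbouring genes, 100% were above 0.2 on X (0.45 to 0.84) and 100% below -0.2 on chromosome 14 (-0.73 to -0.23), which is consistent with a difference in chromosome copy number between the lines. On chromosome 15, 87.0% of the runs were below -0.2 (-0.44 to -0.14). Runs of the other chromosomes were not examined. The copy number hypothesis was found and tested on the same data, and DNA was not measured.

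Ribosomal protein genes were higher, as given above. Matched random sets reached a median of at most 0.14 against 0.44 relative to all genes. Reads moved from pseudogenes are argued against by a median of 0.21 over 41 pseudogene rows. The median log2 fold change was 0.45 before and 0.46 after chromosome centring, so chromosome shifts do not account for that median. A biological difference between the lines stays open as a hypothesis.

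Of the 10 splits of the 6 libraries, 1 gave as many genes as the real one, the real split itself, with 8942 against 1 at most in another. For lists, 2 gave as many, with 9 against 10 at most in another, and each of the 9 other splits called 4 to 10 lists at the preset correlation. With 10 splits the share is never under 0.1. Each other split puts libraries of both groups on both sides, so the difference between the groups enters its spread. Few gene calls were therefore fixed in advance in these splits. Part of the group difference also remains between their sides, so their list calls do not show what no difference would give. Neither count tells the result apart from chance.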
